A study of Mus musculus with 4 samples.

How the data were processed

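RNA of 4 samples of CCE mouse embryonic stem cells, 2 labelled Eif4a2 knockdown and 2 labelled control, was sequenced as poly(A) libraries from 1 µg of total RNA with single-end reads of 100 bp on a HiSeq instrument, per the labels' protocols. The treatment protocol names 2 shRNAs against Eif4a2 and 2 control shRNAs, and the labels do not say which sample received which. Per the submitters' processing notes, which list names without roles, the tools were Bowtie2 2.3.4.3, SAMtools 1.9, HTSeq 0.11.2 and edgeR 3.26.8, with genome build mm9. The annotation release and the strand setting of the counting are not given in the sources used here.

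The deposited table holds, for 32592 genes, a normalized signal per sample and the authors' own comparison. The deposited signal is gene counts divided by an effective library size and expressed as CPM on that size, as its values show. Each value is a whole multiple of the worth of 1 read within a tolerance of 0.001, for 100% of the values, and the columns sum to between 935177 and 1041857. Per the file headers, the deposited comparison gives a log2 fold change and an average log2 CPM, a likelihood ratio score, and a p-value with its adjusted value. No values were pooled over samples, and every per-sample column was used.

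Groups were taken from the sample labels, and columns were matched to samples by name. The test fixed before the data were examined was edgeR's quasi-likelihood test on counts, with limma on log2(value + 1) as the stated fallback where a table holds no counts. Because the table holds normalized values, limma 3.58.1 in R 4.3.3 was applied to log2 of the signal plus a pseudocount of 1, so fold changes are on that scale and understate the change of low genes. The deposited scaling was kept for the main fit. Genes were kept where edgeR 4.0.16's filterByExpr passed on the recovered reads, which left 14890 genes. Empirical Bayes moderation used a variance trend, a choice not fixed in advance. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg, and genes with an adjusted p below 0.05 were called. An exact permutation test of 2 against 2 cannot go below 0.333, so calls rest on the variance shared across genes. The words rose and fell refer to the libraries labelled knockdown relative to the libraries labelled control.

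Gene names and IDs were taken from the table, which pairs 32590 of its genes with a symbol; 32590 genes matched GENCODE M21 by ID, which gave GC content, transcript length and chromosome. Coordinates are those of GRCm38 in that annotation, a different build from the authors' mm9, and none was converted. In advance, 28 gene lists were fixed, of which 852 genes matched the table. Lists with at least 5 genes tested were compared with all other genes by camera, in limma, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. With an estimated correlation per list in place of the preset one, camera called 0 of the 28 lists, and 0 had an unadjusted p below 0.05. With the preset one 15 were called. The estimated form also takes its degrees of freedom from these few libraries, so a lost call does not by itself show correlation within a list. Fibroblast markers, with an estimated correlation of -0.007, below the preset one, went from a camera p of 0.00256 to 0.0795. The other called lists had estimated correlations above the preset one, from 0.025 (unfolded protein response) to 0.832 (replication-dependent histones). Ribosome biogenesis stood at 0.72, p53 targets at 0.396 and the ATF4 list at 0.294. Where genes of a list correlate by more than the preset 0.01, the camera p with the preset one is too small. The rotation test fry, which asks whether a set's genes move on balance one way, called 0, and 14 had an unadjusted p below 0.05.

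The genes named were fixed by a rule in advance. It takes Eif4a1, Eif4a2, Eif4a3, H3f3a, H3f3b, Pou5f1, Nanog, Sox2 and Ddx6 whatever their values. It takes the 10 genes that rose and the 10 that fell with the largest change among called genes with an average log2 CPM of at least 3, both libraries of a group on the same side and a symbol that is not a clone or prediction name. In each list it takes up to 4 called members with the smallest p, or up to 2 members given as values where no member passed. Genes outside this rule are said to have been chosen after their values were seen. Some genes that the rule takes are not reported here.

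Replicates were compared before they were averaged. The chi-square of recovered reads per degree of freedom was 2 between knockdown 1 and 2 and 13.8 between control 1 and 2, and Pearson's r of log2 values was 0.996 and 0.986, so no libraries were treated as duplicates. The libraries held between 4604200 and 13681765 recovered reads. Intervals and floors cover counting error only, since PCR reads without molecular identifiers are not independent molecules. The analysis was tested on data simulated from the means and library sizes of the 14890 genes of this comparison with 200 genes changed. There limma recovered 44.8% of genes changed 1.5-fold (30 genes), 82.1% of those changed 2-fold (55) and 97% of those changed 4-fold (64). The false calls numbered 17. Genes were drawn independently, with 1 dispersion per gene shared by both groups. In the data control 1 and 2 differed more than knockdown 1 and 2, so the simulation does not give the share of false calls there.

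Alternatives fixed in advance were RLE scaling, upper-quartile scaling and library size only, no filter on low counts and a filter of 1 CPM in at least 2 samples. Also fixed in advance were DESeq2 1.42.0, limma-voom and edgeR's likelihood ratio and robust fits on the recovered reads, stricter thresholds, the replicate number as a block, leaving out each library, and other set tests. A fit that leaves 1 library in a group takes its spread from the other group alone. Chosen after seeing the data were edgeR's quasi-likelihood test on the recovered reads, pseudocounts of 0.5 and 3, no variance trend, GC and length corrections by loess per library, thinning to the shallowest library, and the block with GC correction.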

Results

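Messenger RNA was measured by poly(A) RNA sequencing in CCE cells, a mouse embryonic stem cell line of 129/Sv origin, grown without feeder cells in medium with leukemia inhibitory factor. The cells had been infected with short hairpin RNAs (shRNAs) against Eif4a2 or with control shRNAs, and were collected on day 4.5 after 3 days of selection in 1 µg/mL puromycin. There were 4 libraries, with 2 samples labelled Eif4a2 knockdown and 2 labelled control. The table listed 32592 genes as normalized counts (CPM on an effective library size), and whole reads could be recovered from every column. The recovered totals were 10646302 and 12009899 reads in knockdown 1 and 2, and 13681765 and 4604200 in control 1 and 2. Control 2 was thus the shallowest library, and 3 reads in it corresponded to 0.679 normalized counts, against 0.221 to 0.266 in the other libraries. Nothing in the labels says that the samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

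The first comparison asked how the targeted gene itself stood in each library. Eif4a2 (ENSMUSG00000022884, chromosome 16, 23107444 to 23114136 on the plus strand of GRCm38) encodes an RNA helicase that acts in translation initiation and in mRNA repression. It was at 752.5 and 814 normalized counts in the libraries labelled knockdown and at 530.6 and 379 in the libraries labelled control. The means were 783.3 ± 43.5 and 454.8 ± 107 (SD, n = 2 each), so the targeted transcript was 1.74-fold higher in the libraries labelled knockdown (log2 change 0.80, SE 0.15, limma adjusted p = 0.014). In the authors' deposited table the log2 fold change of Eif4a2 was 0.78 with an adjusted p of 9.32e-05, in the same direction. The targeted gene thus goes against its label, and every direction given here is that of the libraries labelled knockdown relative to the libraries labelled control, not that of a measured loss of Eif4a2. Without a variance trend in limma, Eif4a2 did not pass (adjusted p = 0.0581).

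Its closest paralog, Eif4a1, a helicase of the cap-binding complex eIF4F, fell from 247.7 ± 3.99 to 176.4 ± 10.9 normalized counts (log2 change -0.49, SE 0.08, limma adjusted p = 0.0102). Eif4a3, the paralog of the exon junction complex, was at 156.5 ± 8.33 in the libraries labelled knockdown and 161.2 ± 28 in the libraries labelled control, with no detectable difference (log2 change -0.03, limma adjusted p = 0.865). This log2 change of Eif4a3 was 0.005 with upper-quartile scaling, 0.09 with library size only and -0.21 without control 1. Of the 2 genes that encode histone H3.3, H3f3b fell 1.56-fold, from 623.8 ± 89.8 to 397.9 ± 4.77 (log2 change -0.64, SE 0.11, limma adjusted p = 0.0104). H3f3a was listed at 8.83 to 11 in the 4 libraries and did not pass the test (log2 change 0.03, limma adjusted p = 0.923), a low level that is uncertain because this gene has near-identical copies that can share its reads. Ddx6, an RNA helicase of processing bodies, fell from 430.4 ± 25.7 to 281.2 ± 20.2 (log2 change -0.61, SE 0.09, limma adjusted p = 0.00715). Without knockdown 2, Eif4a1 (adjusted p = 0.147) and Ddx6 (adjusted p = 0.0652) did not pass in limma; without a variance trend, Eif4a1 and H3f3b did not pass.

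**Figure D1:**
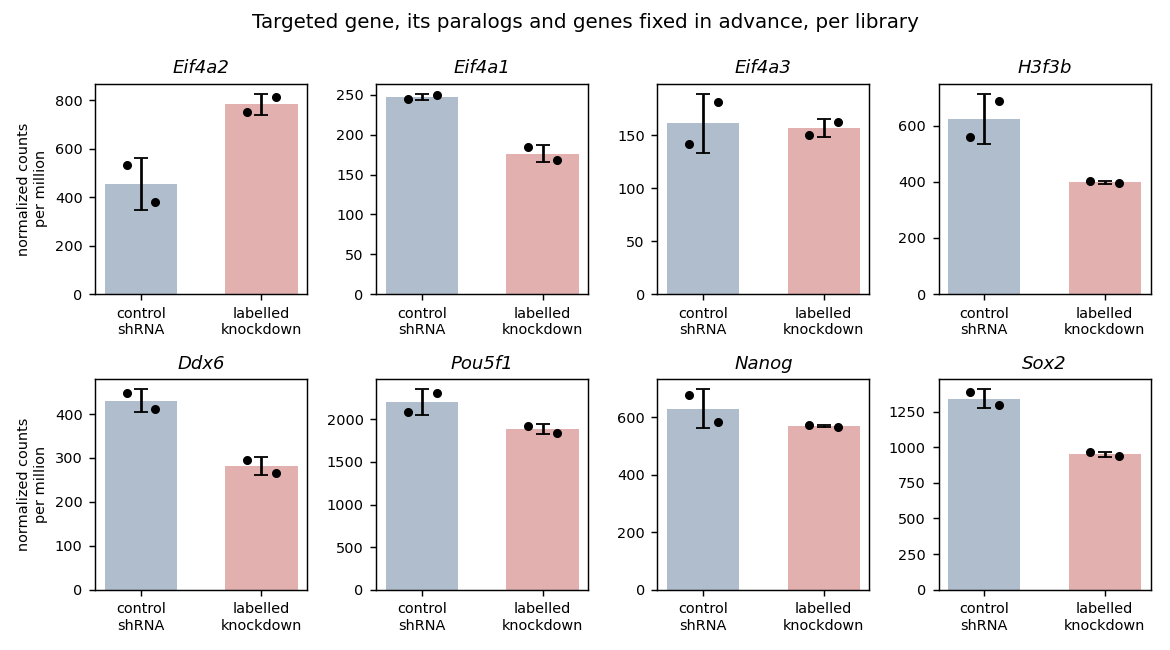
Normalized counts (CPM; y axis) of Eif4a2, its paralogs and genes named in advance, in the libraries labelled control and labelled knockdown (x axis). Bars are means of 2 libraries, error bars SD and points single libraries; Eif4a2 lies at 752.5 and 814 in the libraries labelled knockdown and at 530.6 and 379 in the libraries labelled control.

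The second comparison asked which genes differed between the groups. Of 14890 genes tested with limma, 3418 passed at a Benjamini-Hochberg adjusted p below 0.05, of which 1567 rose and 1851 fell in the libraries labelled knockdown, and 469 rose and 206 fell at least 2-fold. Among the genes that rose most were the transcription factors Foxj1 (37.3 ± 3.35 against 11.2 ± 7.81 normalized counts, 3.52-fold), which drives the formation of motile cilia, and Mlxipl (3.41-fold), a glucose-responsive regulator of metabolic genes. Trim47 (4.34-fold), Cnga3 (3.62-fold), a cyclic nucleotide-gated channel subunit, Slc43a3 (3.5-fold) and the Wnt receptor gene Fzd2 (37.2 ± 1.19 against 9.95 ± 0.647, 3.49-fold) rose too. So did the rows Mir293 (3.43-fold) and Mir291b (3.42-fold), which lie in a microRNA cluster of embryonic stem cells. The largest falls among the named genes were of noncoding RNAs. The small nucleolar RNA Rnu3a was at 33.1 ± 28.1 in the libraries labelled control against 0.706 ± 0.00669. The RNA parts of RNase MRP and RNase P fell too, Rmrp (275.6 ± 260 against 13.2 ± 3.45) and Rpph1 (18.1 ± 12.5 against 1.3 ± 0.296). Ccdc107, which overlaps Rmrp on the opposite strand in the GRCm38 annotation, fell 4.45-fold, and no source says that the counting used strand, so reads of the pair cannot be told apart. Egr1, an immediate early transcription factor, fell 3.5-fold (59 ± 18.9 to 15.8 ± 2.05), Chac1, a glutathione-degrading enzyme, 4.23-fold, Slc11a1 3.78-fold, Pou2f3 3.71-fold, Soga3 3.54-fold and the histone gene H4c4 5.25-fold. The limma adjusted p of these genes lay between 0.00256 and 0.0289. The rule that named them required a call and both libraries of a group on the same side of both libraries of the other. Rmrp and Ccdc107 did not pass in the robust edgeR fit (adjusted p = 0.122 and 0.145), and Foxj1, H4c4, Ccdc107, Chac1 and Pou2f3 did not pass without a variance trend in limma. Several of these changes rested on the spread of the controls. Without control 1 and without control 2, the log2 change was 2.78 and 1.45 for Trim47, 2.52 and 1.11 for Foxj1, -4.98 and -3.06 for Rnu3a, and -5.04 and -2.73 for Rmrp. It was -3.61 and -2.16 for Rpph1, -3.12 and -1.19 for Ccdc107, -3.29 and -1.50 for H4c4, -2.78 and -1.38 for Chac1, and -1.22 and -2.57 for Pou2f3.

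A fit that left out a library took its spread from the 2 libraries of the other group alone. The median absolute log2 difference was 0.198 between control 1 and 2 and 0.095 between knockdown 1 and 2. Fewer calls without a knockdown library and more without a control library can follow from this alone. Counts of list members given below for such fits carry the same limit. With library size as the only scaling, the median of all genes moved by 0.11 on the log2 scale and 2152 genes rose and 996 fell. By that scaling 68.4% of the calls rose, against 45.8% as deposited. The edgeR quasi-likelihood test on the recovered reads, of which 100% came out whole, called 3742 genes (1784 rose and 1958 fell). By the authors' deposited table, a total of 3754 genes passed the same threshold, and 3089 of the 3418 genes passed in both with the same sign. Across genes, the log2 change rose with the GC content of the transcripts (Spearman's rho 0.269 over 14890 genes, which are not independent replicates). In all, 127 genes rose and 576 fell in the fifth lowest in GC, and 566 rose and 184 fell in the fifth highest. The groups did not overlap for 66.8% of the genes tested, against 33.3% by chance for 2 against 2.

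Genes of pluripotency, the state of embryonic stem cells, were lower as a group in the libraries labelled knockdown. Of 34 members tested, 11 fell, 2 rose and 21 did not pass, and 14 fell and 2 rose when adjusted over the list alone (median log2 change -0.21, camera adjusted p = 0.000273). Zfp42 fell 2.09-fold (1012 ± 61.8 to 483.8 ± 4.05 normalized counts), Nr0b1 2.39-fold, Klf4 1.81-fold (793.9 ± 14.2 to 437 ± 5.75) and Tet1, a 5-methylcytosine oxidase, 1.67-fold, while Lefty1 and Fbxo15, chosen after their values were seen, rose. Sox2 fell from 1340 ± 65.1 to 950.5 ± 19.2 (log2 change -0.50, SE 0.09, limma adjusted p = 0.0114). Pou5f1 (log2 change -0.22, SE 0.10, limma adjusted p = 0.145) and Nanog (log2 change -0.14, SE 0.10, limma adjusted p = 0.31) did not pass. With an estimated correlation the list was not called (adjusted p = 0.459 with an estimated correlation). Without knockdown 1, knockdown 2, control 1 or control 2, the members that fell numbered 10, 9, 23 and 19, and those that rose 1, 0, 3 and 6. The median was -0.35 without control 1 and -0.09 with library size only. Fibroblast markers, of a possible other cell type, moved opposite to this list. They were higher in the libraries labelled knockdown (median 0.48, camera adjusted p = 0.00596, and 0.459 with an estimated correlation). Among them Cald1 rose 2.21-fold, while Fn1, chosen after its values were seen, fell 1.3-fold. The lists below shifted up or down between the same libraries. Sox2 did not pass without knockdown 1 (adjusted p = 0.0937) or knockdown 2 (adjusted p = 0.157).

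Genes of formative and primed pluripotency, the states that come later in the embryo, moved both ways. Otx2 rose 1.97-fold (53.4 ± 0.285 to 106.2 ± 1.92), Car4 5.3-fold and Dnmt3b, chosen after its values were seen, 1.69-fold, while the MAPK pathway targets Etv5 and Dusp6 fell 1.45-fold and 1.86-fold. Of 19 members, 4 rose and 4 fell, and 6 and 5 when adjusted over the list alone, and the list was not called (median log2 change 0.17, camera adjusted p = 0.264). It was called without control 2 (adjusted p = 0.00372), with a median of 0.46, while without control 1 the median was 0.05 (adjusted p = 0.823), with 7 members that rose and 8 that fell. With library size only the median was 0.29.

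Genes of the 2-cell-stage embryo were higher in the libraries labelled knockdown, at low levels. Zscan4d, a telomere and genome activation regulator of that stage, had 36 and 62 reads in the libraries labelled knockdown and 2 and 1 in the libraries labelled control, a ratio of 24.4 (95% exact interval 8.11 to 120, counting error only). Usp17le had 18 and 25 reads against 0 and 0, at least 10.7-fold higher over the floor of 3 reads in the control group. Gm8300 had 20 and 33 reads against 3 and 1, a ratio of 9.9 (95% interval 3.65 to 37.7). Zfp750 rose 1.74-fold, from 13.6 ± 2.61 to 24.2 ± 0.015 normalized counts. Of 33 members matched, 11 were expressed enough to be tested. Of these 6 rose and 1 fell, over all genes and adjusted over the list alone (median log2 change 0.80, and 0.80 with the gene at 0 placed at its bound; camera adjusted p = 0.0321). Zscan4d, Usp17le and Gm8300 belong to families of near-identical copies, and the assignment of their reads is uncertain. The list was not called with an estimated correlation (adjusted p = 0.459 with an estimated correlation), without control 2 (adjusted p = 0.0703), with library size only (adjusted p = 0.0559) or after thinning to equal totals of reads (adjusted p = 0.122). The median was 0.13 with no filter on low counts and 0.43 with a pseudocount of 3, and the list was called in both. The members that rose numbered 4, 1, 7 and 6 without knockdown 1, knockdown 2, control 1 and control 2.

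Genes of the germline and of meiosis rose as a group in the libraries labelled knockdown. Of 28 members, 10 rose and 0 fell in limma (13 rose with library size only), and 18 rose and 1 fell when adjusted over the list alone (median log2 change 0.67, camera adjusted p = 1.02e-05). Stra8, a meiotic entry gene, rose 2.53-fold (8.18 ± 1.65 to 22.2 ± 3.4), the piRNA pathway genes Piwil2 and Tdrd1 2.03-fold and 2.53-fold, and Taf7l 2.26-fold. Of 22 trophectoderm genes 7 rose and 2 fell, and 10 and 2 adjusted over the list alone (median 0.55, camera adjusted p = 0.00377). Fgfr2 rose 2.29-fold and Esx1 1.93-fold; Sct had 21 and 28 reads against 2 and 1, a ratio of 12.2 (95% interval 3.94 to 61.2); Tead4, a trophectoderm transcription factor, fell 1.77-fold (39 ± 0.429 to 21.6 ± 0.656). Neither list was called with an estimated correlation (adjusted p = 0.459 for both with an estimated correlation). Without knockdown 1, knockdown 2, control 1 and control 2, the germline genes that rose numbered 5, 3, 19 and 17 and the trophectoderm genes 3, 0, 14 and 13.

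Fibroblast markers, included as a possible other cell type in the culture, rose as a group in the libraries labelled knockdown. Of 23 members, 6 rose and 1 fell, and 8 and 1 adjusted over the list alone (median log2 change 0.48, camera adjusted p = 0.00596). Cald1, an actin-binding protein, rose 2.21-fold (117.1 ± 27.4 to 256.3 ± 17.6), Col1a1 2.42-fold (3.14 ± 1 to 8.86 ± 0.47), Pdgfrb 1.91-fold and Ccn2 1.48-fold. Targets of p53, the DNA damage response factor, rose as a group too: 8 of 35 rose and 2 fell, and 11 and 2 adjusted over the list alone (median 0.27, camera adjusted p = 0.00426). Ei24 (1.67-fold), Dcxr (2.16-fold), Phlda3 (1.64-fold) and Cdkn1a (2.18-fold, chosen after its values were seen), a cell cycle inhibitor, rose, and Pml fell 1.53-fold. With an estimated correlation these lists were not called (adjusted p = 0.459 and 0.615 with an estimated correlation), and the p53 list was not called without control 2 (adjusted p = 0.0613). The p53 median was 0.58 without control 1 and 0.14 without control 2. The fibroblast markers that rose numbered 2, 1, 12 and 11 and the p53 targets 7, 5, 25 and 14 without knockdown 1, knockdown 2, control 1 and control 2. By the same order those that fell numbered 0, 0, 3 and 3 and 2, 2, 4 and 8.

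Genes of the ATF4 and amino acid response, which make amino acids and charge transfer RNAs, gave the list with the smallest p and were lower in the libraries labelled knockdown. Of 42 members, 27 fell and 2 rose, and 31 and 3 adjusted over the list alone (median log2 change -0.60, camera adjusted p = 3.81e-09). Asns, asparagine synthetase, fell 2.41-fold (282.3 ± 9.8 to 116.9 ± 11.7 normalized counts), Cth 2.57-fold (80.7 ± 3.35 to 30.8 ± 2.2), the serine synthesis gene Psat1 2.26-fold and Nars, asparaginyl-tRNA synthetase, 2.09-fold. Atf4 itself, chosen after its values were seen, fell from 466.7 ± 95.2 to 246.5 ± 14 (log2 change -0.90, SE 0.14, limma adjusted p = 0.00781). The 2 members that rose, also named after their values were seen, were Ddit4 and Ero1l. Of 23 genes of the unfolded protein response, 8 fell and 2 rose, over all genes and adjusted over the list alone (median -0.18, camera adjusted p = 0.0282). The median of the unfolded protein response was -0.06 with library size only. Herpud1 fell 2.23-fold, the chaperone genes Hspa5 and Hsp90b1 1.54-fold and 1.52-fold, and Crebzf rose 1.6-fold. Neither call held with an estimated correlation (adjusted p = 0.459 for both with an estimated correlation), and the unfolded protein response was not called without knockdown 1 (adjusted p = 0.0871) or control 1 (adjusted p = 0.062) or after thinning (adjusted p = 0.0531). The ATF4 members that fell numbered 22, 17, 34 and 31 and those of the unfolded protein response 3, 3, 10 and 12 without knockdown 1, knockdown 2, control 1 and control 2.

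Genes of cholesterol synthesis were lower in the libraries labelled knockdown. Of 23 members, 12 fell and 0 rose in limma, and 15 and 0 adjusted over the list alone (median log2 change -0.43, camera adjusted p = 3.99e-06; 0 rose in limma under each scaling). Msmo1 fell 2.98-fold (84.2 ± 14.8 to 27.4 ± 1.01) and Sqle 1.74-fold. The call was lost with an estimated correlation (adjusted p = 0.459 with an estimated correlation). Without knockdown 1, knockdown 2, control 1 and control 2, the members that fell numbered 5, 5, 16 and 19.

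Translation initiation factors were lower as a group in the libraries labelled knockdown. Of 31 members, 9 fell, 1 rose (Eif4a2 itself) and 21 did not pass, and 12 fell and 1 rose adjusted over the list alone (median log2 change -0.24, camera adjusted p = 0.000321). The median was -0.12 with library size only. Eif4e2, a cap-binding protein, fell 1.81-fold (236.9 ± 23 to 130 ± 9.11), Eif4h 1.68-fold, Eif5 1.53-fold and Eif2s2 1.48-fold. Ribosome biogenesis genes fell in 11 of 38 cases and 0 rose in limma (1 rose with library size only), and 14 fell adjusted over the list alone (median -0.24, camera adjusted p = 2.82e-05). This median was -0.41 without control 1, -0.11 without control 2 and -0.12 with library size only. Among the genes that fell were Dkc1 (1.61-fold), Rcl1 (1.66-fold), Bysl (1.58-fold) and the RNA polymerase I factor Rrn3 (1.38-fold). Of 29 CCR4-NOT, decapping and P-body genes, which act in mRNA decay, 7 fell and 0 rose in limma (1 rose with library size only), over all genes and adjusted over the list alone (median -0.11, camera adjusted p = 0.0412), and the median was 0.008 with library size only. The decapping enzyme gene Dcp2 fell 2.84-fold (366.7 ± 34 to 128.7 ± 15.4), Pan2 1.39-fold and Pum2 1.35-fold. With an estimated correlation the 3 lists were not called (adjusted p = 0.459, 0.615 and 0.459 with an estimated correlation). The decay list was not called with RLE scaling (adjusted p = 0.0512), upper-quartile scaling (0.0632), library size only (0.168), after GC correction (0.267), after thinning (0.0886) or without knockdown 2 (0.0668) or control 1 (0.0658). The members that fell without knockdown 1, knockdown 2, control 1 and control 2 numbered 7, 2, 21 and 17 for initiation, 3, 3, 32 and 16 for ribosome biogenesis and 2, 1, 11 and 12 for decay. Those that rose numbered 1, 1, 3 and 3, then 0, 0, 0 and 4, then 0, 0, 4 and 2.

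The list of histone H3.3 genes and their chaperones had 4 of 11 members that fell and 0 that rose in limma (1 rose with library size only), with the same counts adjusted over the list alone. Besides H3f3b these were Ubn1 (1.49-fold), Asf1b (1.36-fold) and Nasp (1.29-fold), which bind or deposit histone H3 variants. The list as a whole was not called (median log2 change -0.26, camera adjusted p = 0.0661; adjusted p = 0.459 with an estimated correlation). It was called with no filter on low counts (adjusted p = 0.0215), without knockdown 2 (adjusted p = 0.0399) and without control 1 (adjusted p = 0.0165), but not without control 2 (adjusted p = 0.139), where its median was -0.11 (-0.42 without control 1, -0.14 with library size only).

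Genes of DNA replication and mitosis were lower in the libraries labelled knockdown. Of 29 S phase genes, 9 fell and 1 rose, and 17 and 1 adjusted over the list alone (median log2 change -0.25, camera adjusted p = 1.65e-05). With library size only 4 fell and the median was -0.13. Slbp, which binds histone mRNAs, fell 1.9-fold (93.8 ± 8.16 to 48.9 ± 2.47), the replicative helicase genes Mcm6 and Mcm3 1.56-fold and 1.49-fold, and E2f1 rose 1.43-fold. Of 31 genes of G2 and M phase, 6 fell and 0 rose in limma, over all genes and adjusted over the list alone (median -0.13, camera adjusted p = 0.00143). With upper-quartile scaling 4 fell and with library size only 3, with 0 that rose under each scaling; the median was -0.004 with library size only and -0.21 without control 2. They included the mitotic kinase gene Ttk (1.83-fold), the motor gene Kif11 (1.6-fold), Nek2 (1.45-fold) and Ndc80 (1.39-fold). With an estimated correlation neither list was called (adjusted p = 0.459 for both with an estimated correlation). Without knockdown 1, knockdown 2, control 1 and control 2, the members that fell numbered 4, 1, 22 and 19 for S phase and 3, 2, 13 and 19 for G2 and M phase.

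Replication-dependent histone genes, whose mRNAs end in a stem-loop in place of a poly(A) tail, were the list with the largest median shift. Of 28 members, 14 fell and 0 rose in limma (13 fell with upper-quartile scaling, 12 with library size only, and 0 rose under each scaling), and 21 fell adjusted over the list alone (median log2 change -1.20, camera adjusted p = 6.46e-07; adjusted p = 0.545 with an estimated correlation). H2bc8 was at 6.32 ± 3.22 normalized counts in the libraries labelled control and 0.661 ± 0.0561 in the libraries labelled knockdown, and H1f5 at 9.05 ± 3.85 and 1.82 ± 0.0659. By the same order H4c2 was at 9.63 ± 6.22 and 1.25 ± 0.234, and H1f3 at 10.8 ± 3.98 and 3.45 ± 0.144. Other RNA classes without a long poly(A) tail gave unlike medians. Of 13 genes of such classes other than small nucleolar RNAs 7 fell and 0 rose, with a median of -0.91. Terc, chosen after its values were seen, stood at 0.96 (limma adjusted p = 0.18). Of 72 small nucleolar RNAs 8 fell and 2 rose, with a median of 0.007. Many of them lay at few reads, where the pseudocount of 1 pulls log2 changes toward 0. Control 2 exceeded control 1 by a median log2 of 0.58 in the 13 genes, 0.24 in the small nucleolar RNAs and 1.16 in the histones. Rmrp was at 91.8 in control 1 and 459 in control 2, against 15.6 and 10.8 in the libraries labelled knockdown. In the same order, the mitochondrial ribosomal RNA mt-Rnr1, chosen after its values were seen, was at 712 and 997 against 329 and 320. The histone genes that fell numbered 10, 9, 26 and 15 without knockdown 1, knockdown 2, control 1 and control 2, with medians of -1.19, -1.34, -1.82 and -0.79.

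**Figure D2:**
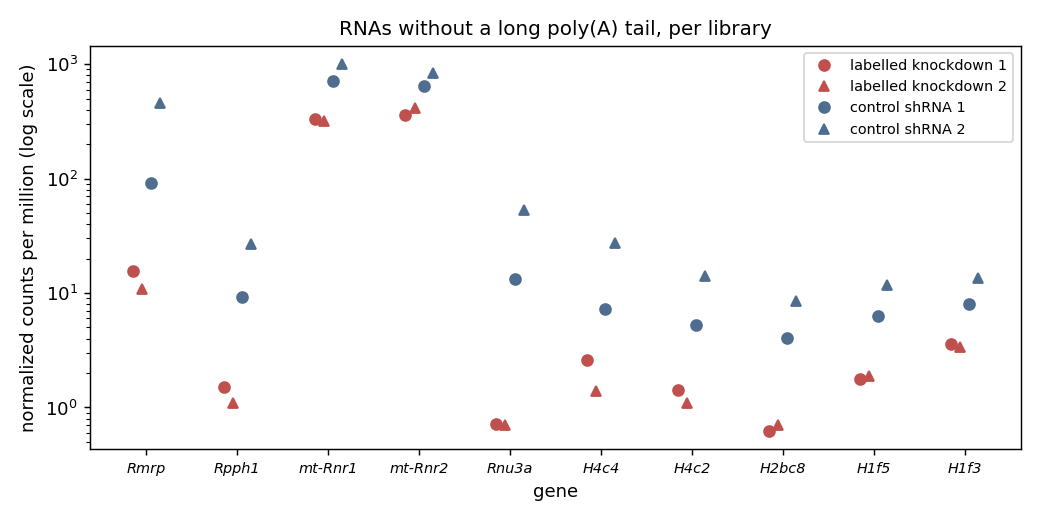
Normalized counts (CPM; y axis, log scale) of RNAs without a long poly(A) tail and replication-dependent histone genes (x axis), one point per library. Both libraries labelled control lie above both labelled knockdown for each gene drawn, and control 2 lies above control 1. The genes drawn are called genes that fell, and mt-Rnr1 and mt-Rnr2 were chosen after their values were seen, so they do not stand for all such RNAs. Terc, which went the other way, is not drawn.

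The remaining lists were not called. Lineage markers moved both ways: among 17 mesoderm genes 3 rose (among them Tal1 2.53-fold and Snai1 2.83-fold) and 1 fell (Bmp4, 2.38-fold; camera adjusted p = 0.154). Among 25 primitive and extraembryonic endoderm genes 4 rose and 3 fell (adjusted p = 0.161), with Serpinh1 up 1.88-fold, Sparc up 1.61-fold, Lama1 down 2.2-fold and Fst down 2.35-fold. Of 19 neuroectoderm genes 7 fell and 1 rose (median -0.41, camera adjusted p = 0.095), including Sox21 (2.9-fold), Ncam1 (1.95-fold), Stmn2 (2.28-fold) and Nefl (1.94-fold). This list was called without knockdown 1 (adjusted p = 0.0113), knockdown 2 (0.0179) or control 1 (0.00218), after GC correction (0.0389), with library size only (0.0222), with a filter of 1 CPM and after thinning. Of 25 imprinted genes 10 rose and 6 fell (camera adjusted p = 0.166), with Meg3 up 4.89-fold and Zdbf2, Mest and Impact down 2.06-fold, 1.97-fold and 1.69-fold. Interferon response genes gave 4 that rose and 3 that fell of 27 (adjusted p = 0.5), with Tap1 up 2.85-fold, Irf1 up 1.6-fold, Ddx58 down 3.37-fold and Dtx3l down 1.56-fold. Of 19 MAPK immediate early and feedback genes 3 rose and 5 fell (adjusted p = 0.946), with Phlda1 up 2.27-fold and Klf6 and Spry4 down 1.61-fold and 2.01-fold. In the microRNA pathway 2 of 15 rose, Tnrc6b (1.55-fold) and Ago1 (1.45-fold), and 2 fell, Trim71 (1.86-fold) and Xpo5 (1.37-fold; adjusted p = 0.788). Adjusted over the list alone, the genes that rose and fell numbered 3 and 1 for mesoderm, 4 and 3 for endoderm, 1 and 8 for neuroectoderm, and 10 and 6 for imprinted genes. They numbered 4 and 3 for interferon, 4 and 6 for MAPK and 2 and 3 for the microRNA pathway.

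Of 27 genes of glycolysis and hypoxia 3 rose and 5 fell (camera adjusted p = 0.946), with the glycolytic genes Hk2 and Pfkp down 1.43-fold and 1.48-fold, Bnip3 down 2.25-fold and Vegfa up 1.44-fold. Of 30 DNA and histone methylation enzymes 3 rose and 4 fell (adjusted p = 0.5), with the histone methyltransferase subunits Wdr5 and Ash2l down 1.26-fold and 1.28-fold, Kdm5b down 1.34-fold and Kdm6b up 1.34-fold. With library size only the balance turned over, with 5 that rose and 3 that fell in glycolysis and hypoxia and 6 and 1 among the methylation enzymes. Of 76 cytosolic ribosomal protein genes 2 rose and 5 fell (median -0.07, adjusted p = 0.434), with Rplp1 down 1.96-fold, Rplp0 and Rps3a1 down 1.35-fold and 1.4-fold and Rpl15 up 1.32-fold. These genes have many pseudogene copies, and 3 rose and 1 fell with library size only. The median was 0.05 with library size only and without control 2, and -0.15 without control 1. None of the 7 mitochondrially encoded genes tested passed in limma (camera adjusted p = 0.389; 1 had an unadjusted p below 0.05). In the libraries labelled knockdown and labelled control, mt-Nd5 was at 1400 ± 18.2 and 1061 ± 268 and mt-Nd4 at 490.9 ± 3.33 and 402.5 ± 79.3. Adjusted over the list alone, the genes that rose and fell numbered 5 and 6, 3 and 4, 0 and 1, and 0 and 0 in these 4 lists. Counts in the uncalled lists moved with the library left out. The mitochondrial list was called by camera after GC correction (adjusted p = 0.017, with 3 genes that rose). Its median was 0.37 without control 1 and -0.04 without control 2.

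**Figure D3:**
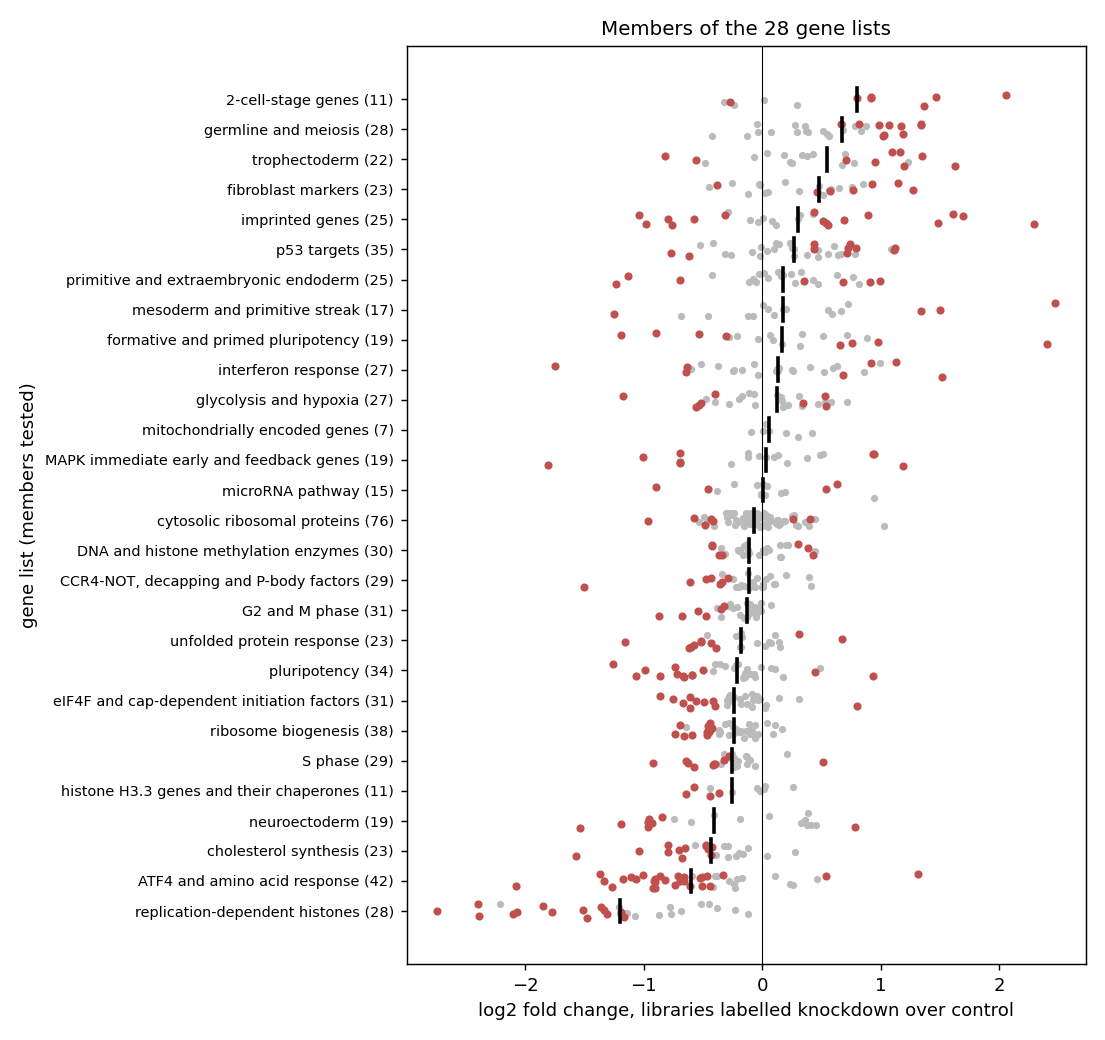
Log2 fold change of the libraries labelled knockdown over the libraries labelled control (x axis) for the members of the 28 gene lists (y axis, with the number tested). Red points passed at an adjusted p below 0.05, grey points did not, and black bars are medians, from -1.20 for replication-dependent histones to 0.80 for 2-cell-stage genes.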

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

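Chosen after seeing the data were edgeR on recovered reads, other pseudocounts, no variance trend, GC and length corrections, thinning, and the block with GC correction. Of 144 named genes, 79 kept their direction and side of the threshold in every setting. The number of genes changed was 3418, against 2192 with DESeq2, 1932 without a variance trend, 772 at an adjusted p below 0.01, 675 at 2-fold or more, and 653 to 7724 when single libraries were left out. There a lone sample is assumed to vary like the other group. Stricter thresholds take fewer genes by construction; the other causes were not tested. Eif4a2 (log2 change 0.80) did not pass without a variance trend (limma adjusted p = 0.0581). The number of lists called was 15, and 0 with an estimated correlation, which has little power with so few libraries, or with fry. The 2-cell-stage median of 0.80 lost its call with library size only (0.92), after thinning (0.41), with an estimated correlation (0.80) and with fry (0.80), and ranged from 0.62 to 0.96 over the fits that left out a library. The pluripotency median of -0.21 lost its call with an estimated correlation (-0.21) and fry (-0.21). The H3.3 list was called with no filter (-0.26), and ranged from -0.42 to -0.11 without single libraries. The CCR4-NOT median reversed with library size only (0.008), as that scaling moved all genes by 0.11. Eif4a3 reversed with upper-quartile scaling (0.005), library size only (0.09) and limma-voom (0.002), and ranged from -0.21 to 0.14 without single libraries. H3f3a reversed with limma-voom (-0.028), the likelihood ratio test (-0.012), the robust fit (-0.005) and edgeR on recovered reads (-0.005), and ranged from -0.11 to 0.17 without single libraries. The cause was not tested. The labels tie same-numbered libraries by number alone. Their correlation of deviations was 0.036 over 2 pairs, which mirror each other, so it cannot exclude a shared batch or order of shRNAs. With GC content, knockdown 1 minus 2 and control 1 minus 2 had like trends (Spearman's rho -0.118 and -0.133). The replicate block gave 4632 genes and 15 lists (neuroectoderm called, CCR4-NOT not), and with GC correction 4039 genes. The depth of 4604200 reads in control 2 limits low genes such as the 2-cell-stage list.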

Other observations

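The tests of the direction of Eif4a2 other than its GC test, the tests of the histone pattern and those of another cell type, were chosen only after the result was seen, and the GC, length and thinning settings were added after seeing the data. Reads in the mir-290 cluster, a microRNA cluster of embryonic stem cells whose rows were singled out after their values were seen, were higher in the libraries labelled knockdown. Of 7 rows, 6 rose and all 7 had both libraries labelled knockdown above both labelled control, with log2 changes from 0.90 to 1.78; Mir295 was at 6.66 and 7.63 normalized counts against 1.4 and 1.81. Mature microRNAs are not captured in poly(A) libraries, so these rows are no measure of them. Among imprinted genes, H19 and Dlk1, also chosen after their values were seen, rose with Meg3, at 3.37 and 5.45 normalized counts against 0.81 and 0.679 for H19 and at 5.51 and 7.4 against 1.69 and 1.58 for Dlk1.

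Eif4a2 was higher in the libraries labelled knockdown. Reads shared with Eif4a1 are argued against by the fall of that paralog (log2 change -0.49), and library scaling by a lowest log2 change of 0.82 for Eif4a2 over 3 other scalings. The shallow control library is argued against by 0.56 without control 2, and a GC trend by 0.95 after GC correction. Exchanged group labels may account for it and cannot be told apart from a real rise. Both libraries labelled control (2 of 2) lie below both labelled knockdown, as an exchange needs, but no value independent of Eif4a2 ties a library to its shRNA. A rise of the transcript in cells that received the shRNA was not tested.

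In all, 3418 genes differed between the groups. A GC trend as the whole cause is argued against by the 3077 genes called after GC correction, of which 2562 were among the 3418. A depth difference is argued against by 2644 genes after thinning to the shallowest library. The length correction, with 3465 genes after it, decides nothing, since length and log2 change had a Spearman's rho of only 0.035 and there was little to remove. Another cell type, such as fibroblasts, as the whole cause of the falls is argued against by Pou5f1 and Nanog. Other cells dilute all genes that only embryonic stem cells express alike, but 31.8% of the genes that fell (589 of 1851) lay below these genes by more than the spread. For the genes that rose it stays open and cannot be told apart from a change within the cells: the fibroblast markers had a median log2 change of 0.48, but 1 of them fell. Gain or loss of a whole chromosome among 1 to 19 and X is argued against by the chromosome medians. The farthest, that of X, lay at -0.082 from the median of all genes. Chromosome Y was not examined, and a gain or loss in few of the cells could go unseen. Since the libraries of a group share their label and may share a preparation, a difference between preparations was not tested, and neither was the effect of the shRNAs.

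Replication-dependent histones were lower in the libraries labelled knockdown. More RNA without poly(A) tails in the control libraries may account for it and cannot be told apart from other causes. The 13 genes of annotated classes without long tails other than small nucleolar RNAs had a median log2 change of -0.91, but with 72 small nucleolar RNAs included the median was -0.07. Many of those RNAs lie in introns of other genes and can share their reads. Many also lay at few reads, where the pseudocount pulls log2 changes toward 0, and of the 72 there were 8 that fell and 2 that rose. Neither median therefore decides. Control 2 exceeded control 1 by 0.58 in the 13 genes and by 1.16 in the histones. Fewer cells in S phase would lower the S phase list, which had a median of -0.25. It would also need control 2 to exceed control 1 in that list as in the histones. That excess was only 0.10 in the S phase list against 1.16 in the histones, which argues against it for the gap between the controls. For the difference between the groups it stays open. A biological effect of the shRNAs on histone transcripts was not tested.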
